A study of Mus musculus with 6 samples.

How the data were processed

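CD8 T cells from spleen and lymph nodes of untreated TCR4 and WT mice were profiled by RNA sequencing, with 3 libraries per genotype that the series describes as biological replicates; the labels put all 6 in 1 batch. Per the labels' protocols, RNA was extracted with a column kit, mRNA was selected with poly-T beads and fragmented, and cDNA made with random primers was size-selected and amplified by PCR. Whether the libraries kept strand, how genes were counted and which annotation was used are not given in the sources used here. Per the submitters' processing notes, HISAT2 2.0.5 and the genome build mm10 were used. Reads of a gene and of an overlapping or antisense gene, or of a near-identical copy, may therefore have been divided in ways that cannot be checked.

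The deposited table holds 25106 genes, 24641 with Ensembl identifiers and 465 unannotated loci. Its per-library values are a signal that the authors made by dividing gene counts by 1 size factor per library, as the deposited values themselves show: within a tolerance of 0.01, 100% of the values in each library were whole multiples of 1 step, and median-of-ratios factors recomputed from the whole reads differed from the deposited scaling by at most 5.0e-10. Per the file headers, the table also holds the authors' log2 fold changes of TCR4 over WT. Per the file headers, each gene has a p-value and an adjusted p-value from the authors; 4 genes have no p-value, and the adjusted one is 1 for 9252 genes. The table's positions do not follow the mm10 annotation: of 23334 genes shared with GENCODE M21, which uses that build, 446 had the same chromosome and start, while 22196 had the same span from start to end. Positions are given as the deposited table gives them, and the build they belong to is not given in the sources used here.

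The tests, the gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined, for raw counts, with limma as the stated substitute if the values were normalised. Because the deposited values are normalised, genes were tested with limma 3.58.1 (lmFit and eBayes with a mean-dependent trend) in R 4.3.3 on log2(value + 1), with genotype as the only term, after keeping the 22633 genes with a mean of at least 1 in a genotype. Calls are two-sided with a Benjamini-Hochberg adjusted p under 0.05. Fold changes on the log2(value + 1) scale understate the change of low genes. Whole reads recovered from the values were used for depth, for TCR segment shares, for floors and, as alternatives, for DESeq2 1.42.0, limma-voom and edgeR 4.0.16. Figures were drawn with Python 3.11.15.

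The 33 gene lists covered CD8 T cell states, NK receptors, signalling, interferon response, cell cycle, metabolism, ribosomal proteins, antigen receptor segments and markers of other cell types; some genes stand in more than 1 list. Each list with at least 5 tested genes was tested with camera on the log2 values with a preset correlation of 0.01 between genes, adjusted over the 33 lists. camera was also run with an estimated correlation, and fry as directional and mixed tests. Named genes were the 10 largest rises and 10 largest falls among called genes with at least 1 CPM in a genotype and no overlap between the genotypes' libraries, leaving out antigen receptor segments, sex-linked genes and predicted genes; the next 5 by p; up to 4 genes per list by p; the 2 Trav and 2 Trbv segments with the largest share in each genotype; and Cd8a, Cd8b1, Cd4 and Cd3e. Only some of the named genes are given singly, and 1 of 3 gene lists added after the results were seen is not reported here. The Trav and the Trbv segment with the highest mean share in TCR4 were compared between genotypes with an exact two-sided permutation test. Its smallest p with 3 against 3 libraries is 0.1.

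Depth was 15594520 to 17618785 reads per library. Where the WT group had no read, folds were bounded with a floor of 3 reads over the group, and with 1 to 3 reads a ratio with a 95% counting interval is given; PCR copies are not independent molecules, so both cover counting error only. The limma step was tested on simulated counts for 21577 genes with the means and spreads of these libraries, in which it recovered 83% of 100 genes changed 2-fold and 93% of 100 changed 4-fold, while 21 of its calls (10.7%) were unchanged genes. The share of wrong calls in that simulation was thus above the nominal 5%. Its changed genes were drawn only from genes with a higher mean than the filter asks, so recovery of lower genes was not tested. It also changed far fewer genes than were called in the data, so neither share carries over directly. Alternatives to the scaling, the filter, the pseudocount, the test, the replicate block and each library were recomputed. Before-and-after checks of gene length and GC content used smooth trends fitted on genes with a mean of at least 100 normalised reads, with intervals from 2000 bootstrap draws.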

Results

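RNA sequencing compared CD8 T cells of TCR4 mice with CD8 T cells of wild-type (WT) mice. The cells were isolated as a total CD8 population from spleen and lymph nodes of untreated animals, with 3 biological replicates per genotype, and polyadenylated RNA was sequenced. The title of the study places it in immunological tolerance and self-reactive CD8 T cells, and the comparison asks which transcripts differ between CD8 T cells of the TCR4 and WT genotypes. The sources used here do not say what TCR4 stands for. Each library held 15594520 to 17618785 reads assigned to genes, with 20814 to 21582 genes detected, and the 10 most abundant genes took 6.42 to 8.63% of the reads. Levels are given as reads divided by the size factor of the library (normalised reads), as mean ± SD with n = 3 per genotype, and differences as log2 fold changes of TCR4 over WT on the log2(value + 1) scale with limma's adjusted p. Cd8a, which encodes the CD8 alpha chain, averaged 22382 ± 186 in TCR4 and 21649 ± 842 in WT (adjusted p = 0.75). The TCR complex gene Cd3e averaged 5307 ± 432 in TCR4 and 5950.5 ± 156 in WT (adjusted p = 0.21). Cd8b1 averaged 23077 ± 2218 in TCR4 and 18170.5 ± 518 in WT (log2 fold change 0.34 ± 0.10 (SE), adjusted p = 0.032). Its p rose to as much as 0.15 when TCR4 replicate 1, TCR4 replicate 2 or any WT replicate was left out, and was 0.079 with total-count scaling. Cd4 stood at 68.4 ± 9.18 against 21.6 ± 11.9 (adjusted p = 0.0067, and 0.076 without WT replicate 1).

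The genotypes also differed in the sex-linked transcripts of the mice. Each TCR4 library carried 6265 to 6878 reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty and at most 4 reads of Xist, the RNA of the inactive X chromosome. No WT library carried a read of these Y-linked genes and each held 10525 to 12388 Xist reads. Ddx3y averaged 2639.97 ± 376 normalised reads in TCR4 and was at least 2687-fold higher than in WT, where the floor was 3 reads over the group. For Eif2s3y and Kdm5d the bounds were 2301-fold and 1259.7-fold. Of 6 sex-linked genes 4 rose and 1 fell, with the same numbers adjusted over the list alone (camera, adjusted p = 1.4e-05; adjusted p = 0.0598 with an estimated correlation). Every difference between the genotypes is thus also a difference between mice with and without Y-linked transcripts. The first principal component held 40.2% of the variance and separated TCR4 from WT libraries, and the second held 19.6% and set TCR4 replicate 1 apart from the rest. Libraries of one genotype correlated at Pearson's r of 0.976 to 0.984 across genes, which are not independent replicates, and no pair of them agreed within counting noise (chi-square per degree of freedom 7.40 to 23.3).

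The T cell receptor beta repertoire differed between the genotypes. Trbv29 (ENSMUSG00000076480; chromosome 6, 41248328 to 41248815 in the deposited table) took 31.03% ± 1.97 in TCR4 and 6.26% ± 0.132 in WT of all Trbv reads, a difference of 24.8 percentage points that was higher in 3 of 3 TCR4 libraries (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries can give). Trbv29 was chosen for its share in TCR4, so this test is not an independent finding. Since what TCR4 stands for is not given, no segment was named in advance, and the share cannot check the genotype label. Trbv19 took 10.6% ± 0.578 against 4.67% ± 0.612 and Trbv16 10.5% ± 0.919 against 10.3% ± 0.245, while Trbv13-2 took 5.89% ± 0.56 against 9.86% ± 0.0588, Trbv12-1 1.01% ± 0.327 against 7.60% ± 0.473 and Trbv2 0.462% ± 0.0132 against 3.43% ± 0.466. Trbv31, chosen after its values were seen, took 10.6% ± 0.763 against 2.44% ± 0.139. Of 25 Trbv segments tested 18 fell and 2 rose, with the same numbers adjusted over the list alone, and their median log2 fold change was -1.72 (camera, adjusted p = 1.7e-14; adjusted p = 0.0598 with an estimated correlation). Trbv reads together made up 195 to 226 CPM (counts scaled to the library total) in TCR4 libraries and 432 to 483 CPM in WT. Shares and levels therefore differ: Trbv19 was not called (log2 fold change 0.21), and Trbv16 was called lower in TCR4 (-0.96). Among alpha chain segments Trav12-2 (ENSMUSG00000096656; chromosome 14, 53853772 to 53854371) took 13.4% ± 2.41 in TCR4 and 5.12% ± 0.71 in WT of Trav reads, 8.24 points higher (exact permutation test, two-sided, p = 0.1, again the smallest possible). Trav12-2 was chosen in the same way as Trbv29, so its test has the same limit. Trav14-1 took 4.84% ± 0.305 against 4.33% ± 0.572 and Trav16n 3.78% ± 0.17 against 4.95% ± 0.58. Of 92 Trav segments 4 rose and 8 fell, the same adjusted over the list alone (camera, adjusted p = 0.18). Without WT replicate 1 none fell, without WT replicate 2 or 3 only 3 fell, and without WT replicate 2 only 2 rose. Trav segments exist as near-identical copies, so how reads were divided between them is uncertain.

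**Figure D1:**
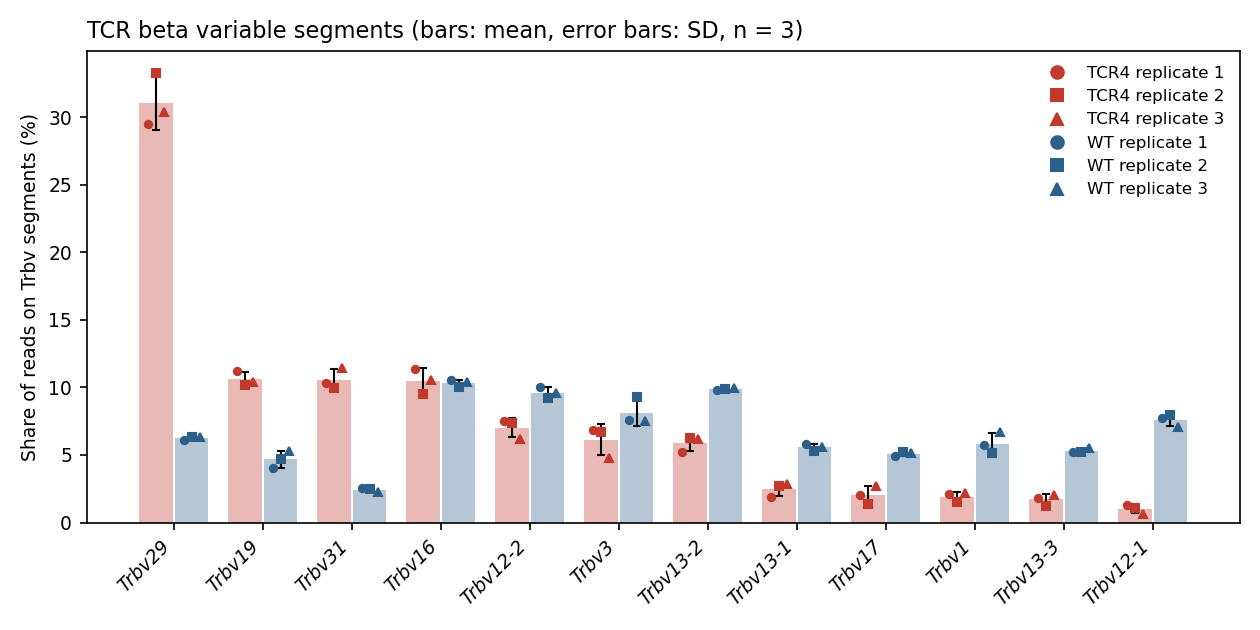
Share of all Trbv reads (percent, vertical axis) taken by the 12 Trbv segments with the largest shares. Bars are means of 3 libraries with SD, points are libraries, red for TCR4 and blue for WT. Trbv29 stands at 29.5 to 33.2% in TCR4 and 6.11 to 6.36% in WT.

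Many genes of memory and cytotoxic T cells rose in TCR4 CD8 T cells. Ly6c2, encoding the surface protein Ly6C of memory CD8 T cells, rose 5.57-fold. Tbx21, encoding the transcription factor T-bet, and Cd44, an activation marker, rose too, while Ccr9, a gut-homing chemokine receptor, fell. In limma, 3784 of 22633 genes passed an adjusted p of 0.05, 2050 higher and 1734 lower in TCR4 (54.2% higher). 971 of them changed at least 2-fold, 560 higher and 411 lower. Without WT replicate 1 the counts were 911 and 353, without WT replicate 2 they were 1690 and 577, and leaving out any other library gave 2730 to 3535 and 719 to 1030. Scaling by total counts called 1473 genes higher and 2480 lower (37.3% higher), with the median of all genes at -0.11 against -0.02, so small changes are relative to the scaling.

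Memory-associated genes passed as a group, upward, in camera at its preset correlation (adjusted p = 5.9e-20) but not with an estimated one (adjusted p = 0.0598). In the directional fry test their adjusted p was 5.9e-04. Ly6c2 (ENSMUSG00000022584; chromosome 15, 74980007 to 74983819 in the deposited table) averaged 19596 ± 2340.5 in TCR4 and 3501 ± 153 in WT (log2 fold change 2.48 ± 0.10 (SE), adjusted p = 7.7e-09). Tbx21 averaged 1325 ± 131 in TCR4 and 321 ± 22.2 in WT (log2 fold change 2.04 ± 0.10 (SE), adjusted p = 8.4e-08). Cd44 averaged 2291 ± 174 against 769 ± 81.7 (log2 fold change 1.58 ± 0.10 (SE), adjusted p = 5.8e-07). Il18rap, a subunit of the interleukin-18 receptor, averaged 2944 ± 409.8 against 720.5 ± 46.7 (log2 fold change 2.02). Of 26 memory and activated CD8 genes 17 rose and none fell (19 and none adjusted over the list alone). Their median log2 fold change was 1.14. Per library the medians over the WT mean were 1.07, 1.43 and 1.14 in TCR4. Of 21 cytotoxicity and effector cytokine genes 15 rose and none fell (16 adjusted over the list alone; 9 without WT replicate 1). The median was 0.86 (camera, adjusted p = 6.3e-14; adjusted p = 0.0598 with an estimated correlation). NK cells and gamma delta T cells share many of these transcripts, and markers of both cell types were higher in the same libraries (medians 1.11 and 0.95). Gzmm, encoding granzyme M, averaged 888 ± 55.3 against 183 ± 18.5 (log2 fold change 2.28 ± 0.11 (SE), adjusted p = 6.4e-08). The chemokine gene Ccl5 averaged 7999.6 ± 1440.1 against 2145 ± 249.8 (log2 fold change 1.89), Nkg7 9167 ± 513 against 4355 ± 425 (1.08) and Ctsw, encoding cathepsin W, 9774 ± 281 against 4996 ± 399.9 (0.97). Gzma and Gzmb, chosen after their values were seen, stood at 289 ± 89.5 against 219 ± 63.2 (adjusted p = 0.28) and 132 ± 21.1 against 109 ± 24.3 (adjusted p = 0.37).

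**Figure D2:**
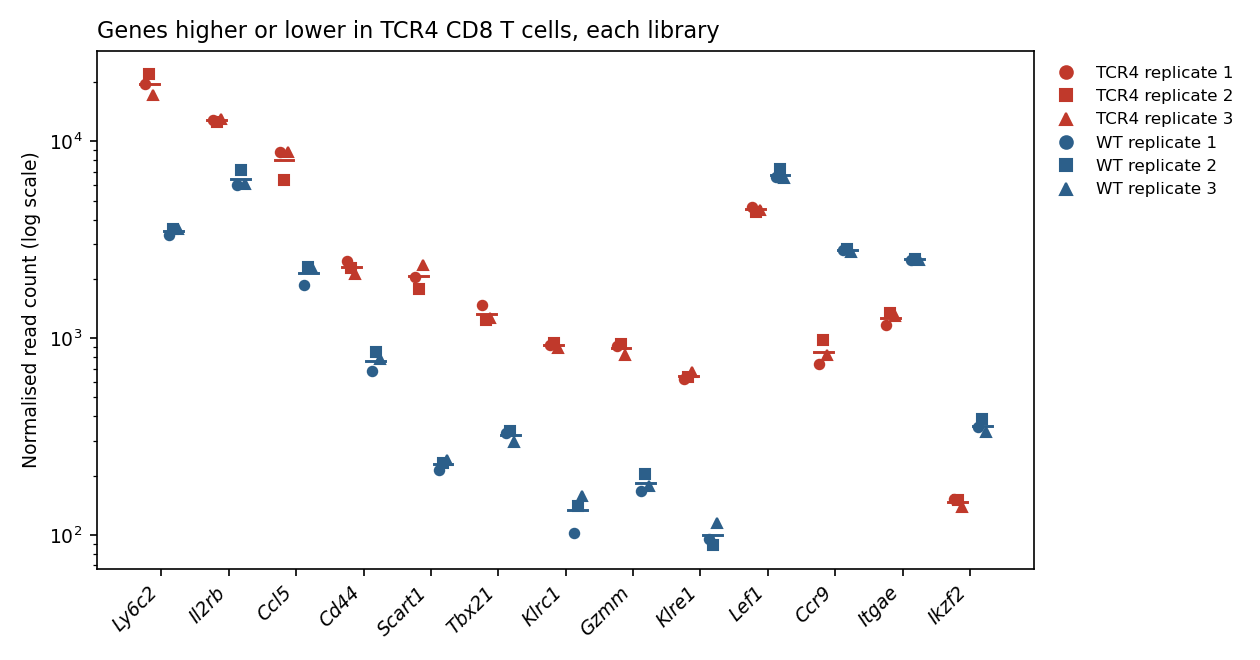
Normalised reads (logarithmic vertical axis) of named genes in each of the 6 libraries. Points are libraries, red for TCR4 and blue for WT, and short lines mark the mean of 3. Ly6c2, Tbx21 and Cd44 lie higher in all 3 TCR4 libraries than in all 3 WT libraries, and Ccr9 lies lower.

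Most NK receptor genes were higher in TCR4. Of 26 NK receptor and CD8 regulatory genes 22 rose and none fell (23 and none adjusted over the list alone). The median log2 fold change was 1.75 (camera, adjusted p = 2.0e-19; adjusted p = 0.0598 with an estimated correlation). Medians per TCR4 library were 1.54, 2.09 and 1.86. Klrc1, encoding the inhibitory receptor NKG2A, averaged 919 ± 24.6 in TCR4 and 134 ± 28.5 in WT (log2 fold change 2.80 ± 0.15 (SE), adjusted p = 1.1e-07). Klre1 averaged 642 ± 25.8 against 99.4 ± 13.3 (log2 fold change 2.69 ± 0.13 (SE), adjusted p = 6.1e-08). Klra7 averaged 318 ± 27.95 against 83.2 ± 22.5 and Klrc2 332 ± 103 against 77.9 ± 7.05, with log2 fold changes of 1.96 and 2.03. Klra5 and Klra17 were among the 10 largest rises, at 84.1 ± 16.6 against 3.77 ± 4.17 and 35.4 ± 11.8 against 1.58 ± 1.41. Klra17 is also a gene of plasmacytoid dendritic cells, whose marker Siglech was higher in all 3 TCR4 libraries. Klra genes, and Klrc1 with Klrc2, are near-identical copies, so the division of reads between them is uncertain. Markers of NK cells moved the same way, but most of them also stand in other lists. Ncr1, Klrb1c, Klra8, Klra4, Tyrobp and Fcer1g are counted among the NK receptor genes too, and Eomes, Prf1, Gzma and Cd244a in further lists. Of the 11 NK cell markers 8 rose (8 adjusted over the list alone), with 3 left without WT replicate 1 and 5 without WT replicate 3. The median was 1.11 (camera, adjusted p = 4.0e-07; adjusted p = 0.11 with an estimated correlation), and TCR4 libraries stood at 0.92, 2.09 and 0.88. Leaving out TCR4 replicate 1 moved it to 1.69. Tyrobp averaged 190.3 ± 44.4 against 39.6 ± 9.94, Klra8 159 ± 26.8 against 25.1 ± 12.4 and Eomes, a T-box factor shared by NK and memory CD8 T cells, 1693 ± 29.4 against 976 ± 129. Ncr1, chosen after its values were seen, stood at 1.00, 68.7 and 21.5 normalised reads in TCR4 replicates 1, 2 and 3 and at 9.27 to 12.5 in WT.

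Among gamma delta and innate-like T cell markers the scavenger receptor genes Scart1 and Scart2 had the largest log2 fold changes. Scart1 (ENSMUSG00000025461; chromosome 7, 139798180 to 139811058 in the deposited table) averaged 2059 ± 291 in TCR4 and 229 ± 13.2 in WT (log2 fold change 3.16 ± 0.11 (SE), adjusted p = 2.4e-09). Scart2 averaged 1790.4 ± 429 against 154 ± 29.1 (log2 fold change 3.52 ± 0.17 (SE), adjusted p = 6.4e-08). Of 11 such markers 6 rose and 1 fell, the same adjusted over the list alone. The median was 0.95 (camera, adjusted p = 1.7e-04; adjusted p = 0.076 with an estimated correlation), and 0.51 without TCR4 replicate 3 and 0.52 without WT replicate 2. Of the 6 rises, 4 are TCR constant regions that are counted again among the TCR gamma and delta segments. Without the TCR and immunoglobulin segments in the fit, 2 of 7 markers rose and 1 fell, with a median of 0.22 and an adjusted p of 0.059 in camera. With all segments in the fit, the 1 fall was lost when any library but TCR4 replicate 1 was left out, and with all libraries it was lost with the replicate block, a pseudocount of 0.1, the CPM filter, DESeq2 and edgeR. Of 17 TCR gamma and delta segments 7 rose and none fell (8 adjusted over the list alone). The median was 1.19 (camera, adjusted p = 1.1e-04; adjusted p = 0.15 with an estimated correlation). 3 rose without WT replicate 1, 3 without WT replicate 2 and 4 without WT replicate 3. Trgc4, a gamma constant region, averaged 151 ± 15.8 against 21.01 ± 3.57 (log2 fold change 2.79 ± 0.24 (SE), adjusted p = 7.9e-06). Trdc, the delta constant region, averaged 214 ± 40.8 against 109 ± 9.19 (log2 fold change 0.95) and Trgv1 27.9 ± 7.29 against 4.23 ± 1.03 (2.46).

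Naive T cell genes moved both ways. Ccr9 (ENSMUSG00000029530; chromosome 9, 123507504 to 123613395 in the deposited table) averaged 847 ± 119 in TCR4 and 2790.2 ± 54.7 in WT (log2 fold change -1.73 ± 0.10 (SE), adjusted p = 3.3e-07). Lef1, a transcription factor of naive T cells, fell from 6765 ± 385 in WT to 4506 ± 111 in TCR4. Bcl2, encoding an anti-apoptotic protein, rose (6296 ± 24.6 against 4012 ± 221), as did Txk, encoding a Tec family kinase (3897 ± 429.98 against 2631 ± 42.9). Of 20 naive and quiescence genes 4 rose and 8 fell (4 and 11 adjusted over the list alone). The median was -0.21 (camera, adjusted p = 0.017; adjusted p = 0.24 with an estimated correlation, and 0.11 without TCR4 replicate 1 at the preset one). Without WT replicate 1, 2 rose and 3 fell, and without WT replicate 2, 2 rose and 4 fell. Of 21 tissue residency and migration genes 6 rose and 3 fell (7 and 5 adjusted over the list alone; camera, adjusted p = 0.34, and 0.034 without TCR4 replicate 1), their median of 0.05 turning to -0.04 with total-count scaling. It was -0.22 without TCR4 replicate 2, 0.38 without TCR4 replicate 1, and 0.15 and 0.17 without WT replicates 2 and 3. Itgb1, an integrin chain, averaged 5472 ± 452 against 2440.2 ± 97.5 and Cxcr5, a follicle-homing chemokine receptor, 502 ± 80.8 against 148 ± 7.32, both higher in TCR4, while Itgae, encoding the integrin CD103, fell (1269 ± 89.9 against 2516 ± 13.9). Of 27 cytokine receptor genes 10 rose and 6 fell (11 and 6 adjusted over the list alone). The median was 0.20 (camera, adjusted p = 0.017; adjusted p = 0.24 with an estimated correlation; 5 and 1 without WT replicate 1, and 2 fell without WT replicate 2). Il2rb, the beta chain of the interleukin-2 and interleukin-15 receptors, averaged 12813 ± 241 against 6412 ± 664, Il18r1 5529 ± 545 against 2267 ± 61.8 and Ifngr1 7598 ± 1122 against 4241 ± 69.5. NK cell markers and B cell markers were also higher in TCR4 (medians 1.11 and 0.71). For B cell markers this held in TCR4 replicates 2 and 3 (1.66 and 1.27) but not in TCR4 replicate 1 (-0.43). The part of such cells in the rises of this paragraph was not tested.

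Inhibitory receptor genes rose in part. Of 21 inhibitory receptor and exhaustion genes 9 rose (10 adjusted over the list alone; 5 without WT replicate 1) and 1 fell (2 adjusted over the list alone; none with any 1 library left out, nor with TMM, no low-value filter, the replicate block, a pseudocount of 5 or edgeR). The median was 0.62 (camera, adjusted p = 9.2e-04; adjusted p = 0.24 with an estimated correlation), and 0.36 without WT replicate 1. Cd38 averaged 221 ± 23.7 against 73.00 ± 11.7 (log2 fold change 1.59 ± 0.18 (SE), adjusted p = 8.9e-05). Lilrb4a averaged 199.6 ± 63.6 against 46.2 ± 4.54 (log2 fold change 2.03), Cd101 332 ± 75.8 against 144 ± 19.3 (1.18) and Cd160 657 ± 27.96 against 408 ± 36.2 (0.69). Myeloid, B and NK cells carry some of these transcripts too, and their markers were also higher in TCR4. In TCR4 replicate 1, however, the medians of myeloid and B cell markers lay within the WT range. Over the WT mean the inhibitory receptor list stood at 0.33, 0.70 and 0.62 in TCR4 replicates 1, 2 and 3, lowest in the TCR4 library where myeloid and B cell markers were lowest. Pdcd1, Lag3 and Tox, chosen after their values were seen, stood at 28.8 ± 2.51 against 38.4 ± 5.88, 121 ± 16.8 against 83.2 ± 32.6 and 543 ± 43.5 against 604 ± 59.2 (adjusted p = 0.39, 0.15 and 0.38). Of 31 TCR signal strength and anergy genes 1 rose and 5 fell (1 and 6 adjusted over the list alone; camera, adjusted p = 0.058). The number that fell was 2 without WT replicate 1 and 2 without WT replicate 2. The number that rose was 6 without TCR4 replicate 1, 2 without TCR4 replicate 2 and 0 without TCR4 replicate 3 or any WT replicate. For this list camera's adjusted p fell to 0.017 without TCR4 replicate 2, 0.0401 without TCR4 replicate 3 and 0.046 without WT replicate 3. With all libraries it was 0.0158 with total-count scaling, where 0 rose and 8 fell, and 0.046 with no low-value filter or with the replicate block. Ikzf2, encoding Helios, fell (147 ± 7.78 against 359 ± 28.1; log2 fold change -1.28 ± 0.13 (SE), adjusted p = 3.1e-05). Of 17 regulatory T cell genes 2 rose and 6 fell, the same adjusted over the list alone (camera, adjusted p = 0.11). Those that fell included Ikzf2 and Itgae and numbered 2 without WT replicate 1 and 3 without WT replicate 3. Those that rose numbered 1 without TCR4 replicate 3 or WT replicate 3 and none without WT replicate 1.

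Proximal TCR signalling genes and apoptosis genes moved in both directions. Lck, the kinase that phosphorylates the TCR complex, averaged 10183 ± 426 in TCR4 and 14448 ± 436 in WT (log2 fold change -0.51 ± 0.08 (SE), adjusted p = 0.0017). Plcg1, encoding phospholipase C gamma, averaged 4079 ± 67.8 against 5504 ± 98.9 (log2 fold change -0.43). Of 26 genes of the TCR complex and proximal signalling 7 rose and 4 fell (8 and 5 adjusted over the list alone; camera, adjusted p = 0.699). There were 4 higher without TCR4 replicate 2, 1 higher and 2 lower without WT replicate 1, and 1 higher without WT replicate 2. Bcl2l1, encoding the survival protein Bcl-xL, averaged 473 ± 21.5 against 211 ± 13.2 (log2 fold change 1.16 ± 0.11 (SE), adjusted p = 2.3e-05). Tnfsf10, encoding TRAIL, averaged 916 ± 103 against 572 ± 29.04. Of 20 apoptosis genes 5 rose and 2 fell (7 and 2 adjusted over the list alone). The median was 0.24 (camera, adjusted p = 0.0198; adjusted p = 0.29 with an estimated correlation), and 0.11 without WT replicate 1 and 0.16 without TCR4 replicate 3. At the preset correlation camera's adjusted p was 0.071 without TCR4 replicate 2, 0.062 without TCR4 replicate 3 and 0.085 without WT replicate 1. 3 rose without WT replicate 1, and of those that fell 1 was left without TCR4 replicate 1, TCR4 replicate 3 or WT replicate 2 and none without WT replicate 1 or 3.

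Type I interferon response genes leaned lower in TCR4. Oas2, encoding an oligoadenylate synthetase, averaged 135 ± 40.8 in TCR4 and 462 ± 31.3 in WT (log2 fold change -1.80 ± 0.18 (SE), adjusted p = 2.8e-05). Oasl1 averaged 76.1 ± 11.1 against 166 ± 8.06 (log2 fold change -1.13). Stat2 and Ifi27l2a fell as well, to 681 ± 45.99 against 1088 ± 40.98 and 923 ± 94.95 against 1462 ± 159.7. Of 31 such genes 2 rose and 8 fell (3 and 11 adjusted over the list alone). The median was -0.31 (camera, adjusted p = 1.0e-04; adjusted p = 0.29 with an estimated correlation), and -0.20 without TCR4 replicate 2. 4 fell without WT replicate 1, while 1 rose without TCR4 replicate 2, WT replicate 2 or WT replicate 3 and none without WT replicate 1. Of 15 MHC genes 1 rose and 4 fell, the same adjusted over the list alone (camera, adjusted p = 0.12, and 0.034 without WT replicate 1). B2m, encoding beta-2 microglobulin, was the 1 that rose (57527 ± 8007 against 37068 ± 2794, adjusted p = 0.0051). Nlrc5, encoding the transactivator of class I genes, was lower (5809 ± 432 against 7899 ± 539.6, adjusted p = 0.0054). Without WT replicate 1 no MHC gene passed (adjusted p = 0.089 and 0.074), and 2 fell without TCR4 replicate 3 and 1 without WT replicate 2 or 3.

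TCR4 replicate 1 stood apart from the other TCR4 libraries for immediate early and cell cycle genes. Median immediate early and dissociation stress levels over the WT mean were -0.51 in TCR4 replicate 1 and 0.55 and 0.48 in TCR4 replicates 2 and 3. Those of cell cycle genes were -1.16, -0.26 and -0.03. Of 20 immediate early genes 2 rose and 1 fell, the same adjusted over the list alone (camera, adjusted p = 0.25). Without TCR4 replicate 1, 11 rose (camera, adjusted p = 3.8e-09), without TCR4 replicate 3 1 rose, and without TCR4 replicate 2 or any WT replicate none rose. The fall, of the heat shock gene Dnajb1 (1511 ± 368 against 2258 ± 147, adjusted p = 0.0093), was lost without TCR4 replicate 3, WT replicate 1 or WT replicate 3 (adjusted p up to 0.14). Of 34 cell cycle genes none rose and 1 fell (none adjusted over the list alone). The median was -0.47 (camera, adjusted p = 5.4e-04; adjusted p = 0.505 with an estimated correlation, and 0.12 without TCR4 replicate 1 at the preset one). Without TCR4 replicate 3, 8 fell, and leaving out any other library left none. The median was -0.77 without TCR4 replicate 3 and -0.11 without TCR4 replicate 1. Mki67, a proliferation marker, stood at 349 ± 204 against 659 ± 148 (adjusted p = 0.059, and 0.030 without TCR4 replicate 3). With all libraries it passed in 5 of 13 other settings, among them total-count scaling, the replicate block and limma-voom, with adjusted p from 0.0071 to 0.26 over the 13. The replicate block called 5 cell cycle genes lower.

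**Figure D3:**
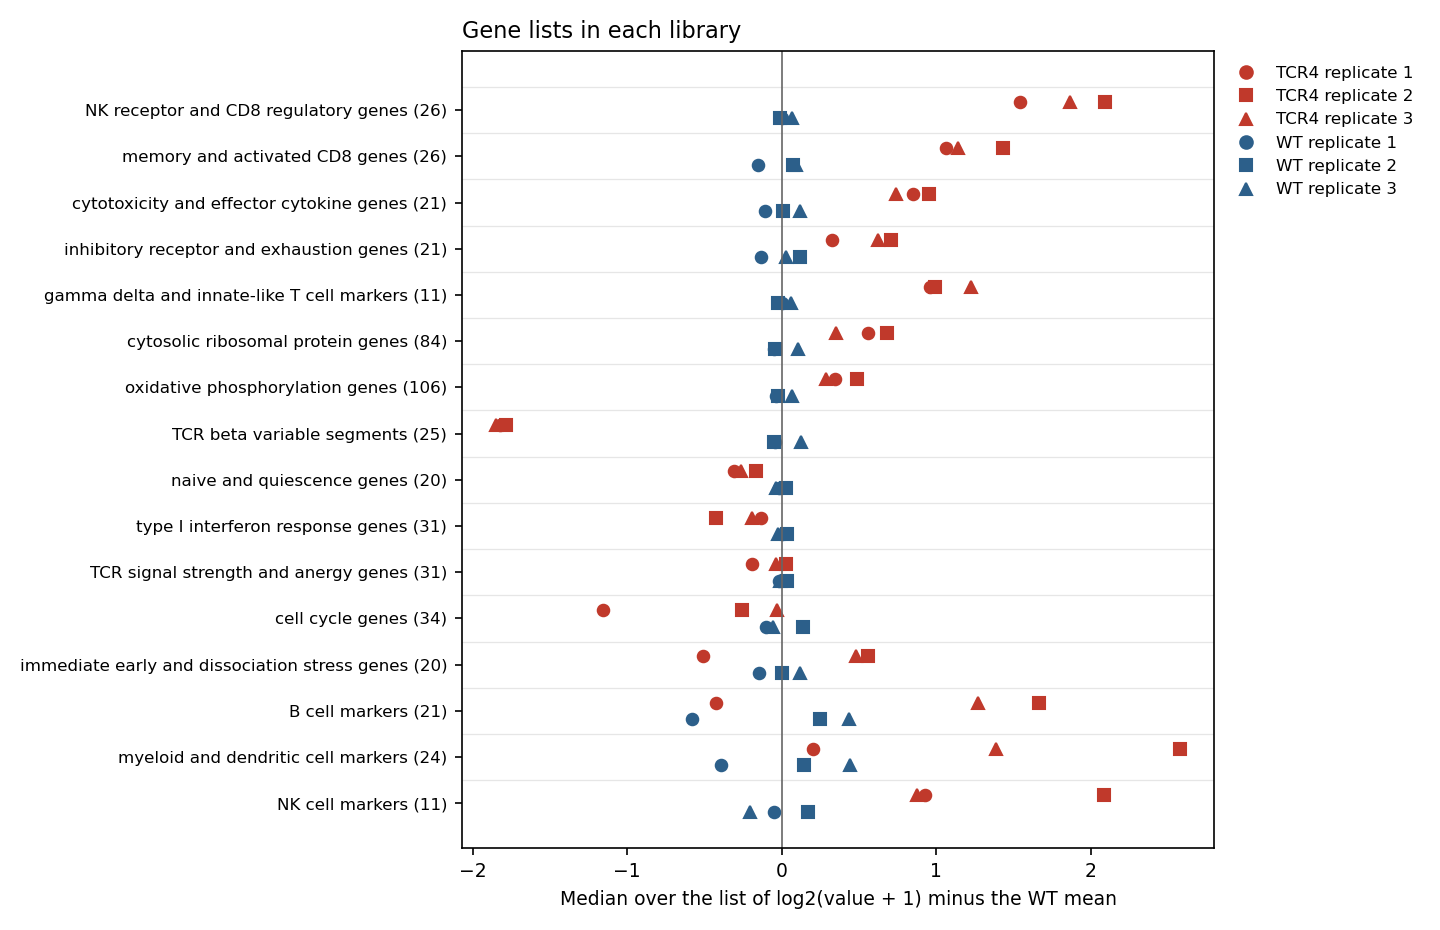
Median over each gene list of log2(value + 1) minus the WT mean (horizontal axis, log2 units) in each of the 6 libraries. Points are libraries, red for TCR4 and blue for WT, with the number of genes tested in brackets. NK receptor genes lie at 1.54 to 2.09 in TCR4 libraries, and TCR4 replicate 1 lies lowest of the TCR4 libraries for immediate early genes (-0.51) and B cell markers (-0.43).

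As list medians, B cell markers and myeloid and dendritic cell markers were higher in TCR4 replicates 2 and 3 than in TCR4 replicate 1, though single genes differed. Medians over the WT mean in TCR4 replicates 1, 2 and 3 were -0.43, 1.66 and 1.27 for B cell markers and 0.20, 2.58 and 1.39 for myeloid and dendritic cell markers. In WT replicates 1, 2 and 3 they were -0.58, 0.25 and 0.44 for B cell markers and -0.39, 0.14 and 0.44 for the others. TCR4 replicate 1 thus lay within the WT range for both list medians. Of 21 B cell markers 8 rose and none fell, the same adjusted over the list alone. The median log2 fold change was 0.71 (camera, adjusted p = 1.7e-04; adjusted p = 0.46 with an estimated correlation). Cd22 averaged 358 ± 101 against 113 ± 25.8 and Spib 130.3 ± 24.9 against 32.1 ± 15.5. The median moved to 1.48 without TCR4 replicate 1, 0.33 without TCR4 replicate 2 and 0.47 without WT replicate 1. The number that rose was 16 without TCR4 replicate 1, 3 without TCR4 replicate 2 or 3, 2 without WT replicate 1 and 5 without WT replicate 2, and 4 in DESeq2 with all libraries. Of 24 myeloid and dendritic cell markers 8 rose and none fell (10 adjusted over the list alone; 16 without TCR4 replicate 1 and 4 without WT replicate 1). The median was 1.26 (camera, adjusted p = 5.7e-07; adjusted p = 0.29 with an estimated correlation), and 1.94 without TCR4 replicate 1 and 0.69 without TCR4 replicate 2. Itgax, encoding CD11c, averaged 421 ± 35.1 against 108 ± 23.8 (log2 fold change 1.97 ± 0.17 (SE), adjusted p = 8.2e-06). Siglech, a plasmacytoid dendritic cell marker, averaged 267 ± 83.2 against 25.9 ± 9.06 (log2 fold change 3.33 ± 0.29 (SE), adjusted p = 8.5e-06) and stood at 362, 227 and 211 in TCR4 replicates 1, 2 and 3. The myeloid genes Cd300c and Cd209d, which stand in no list, were also highest in TCR4 replicate 1, at 35.9, 21.8 and 34.6 and at 55.9, 45.8 and 30.8. Of 161 immunoglobulin segments 8 rose and 1 fell (8 and none adjusted over the list alone; camera, adjusted p = 0.17). Ighv1-75 was at least 15.5-fold higher than the floor of 3 reads over the WT group. Without TCR4 replicate 1, 21 rose (camera, adjusted p = 1.4e-04), without TCR4 replicate 3 4 and without WT replicate 1 1. The fall was lost without TCR4 replicate 3, WT replicate 2 or WT replicate 3. With all libraries 13 rose with the replicate block and in edgeR, and 2 of the 29 left by the CPM filter. For immunoglobulin segments camera's adjusted p was 0.038 and 0.018 without WT replicates 2 and 3.

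Markers of CD4 T cells, plasma cells, erythroid cells, stroma and thymocytes did not pass as lists in camera with all libraries, except that CD4 T cell markers passed when X and Y genes were left out (adjusted p = 0.0289). Of 9 CD4 T cell markers 4 rose and 1 fell, the same adjusted over the list alone (camera, adjusted p = 0.17, upward with a mean of 0.13 against a median of -0.04). With 1 library left out that median ranged from -0.13 to 0.39, the highest without TCR4 replicate 1. Cxcr5 rose, and Zbtb7b, encoding the CD4 lineage factor ThPOK, averaged 123 ± 25.2 against 46.8 ± 10.3. Leaving out WT replicate 1 left 2 that rose, without any 1 WT replicate none fell, and camera's adjusted p was 0.033 without TCR4 replicate 1. None of 6 plasma cell markers passed, over all genes or adjusted over the list alone (camera, adjusted p = 0.22). However, 3 rose without TCR4 replicate 1 (0.014). Jchain stood at 306 ± 212 against 151 ± 92.2 (adjusted p = 0.28, and 8.7e-04 with the replicate block) and Xbp1 at 755 ± 185 against 629 ± 33.4 (adjusted p = 0.34). Of 11 erythroid and platelet markers 1 rose (none adjusted over the list alone; camera, adjusted p = 0.204). It was the platelet gene Ppbp at 13.1 ± 9.58 against 2.22 ± 1.29 (adjusted p = 0.049), whose call was lost without TCR4 replicate 2 or 3 or any WT replicate (up to 0.18). With all libraries it was lost with total-count scaling, no low-value filter, the replicate block, a pseudocount of 0.1 and limma-voom (up to 0.074), and total-count scaling and the replicate block gave 0 higher and 1 lower for the list. Of 8 stromal and endothelial markers 1 rose and 2 fell, the same adjusted over the list alone (camera, adjusted p = 0.66). The rise was lost without WT replicate 1, both falls without TCR4 replicate 2, WT replicate 1 or WT replicate 2, and 1 fall without TCR4 replicate 3. Of 7 thymocyte markers 1 fell, also adjusted over the list alone (camera, adjusted p = 0.67), namely Dntt at 77.8 ± 4.29 against 137 ± 16.3 (adjusted p = 0.0086, and 0.075 without WT replicate 1).

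Many ribosomal protein and oxidative phosphorylation genes rose by small amounts, part of which followed gene length. Of 84 cytosolic ribosomal protein genes 71 rose and none fell (76 and none adjusted over the list alone). The median log2 fold change was 0.52 (camera, adjusted p = 1.4e-28; adjusted p = 0.24 with an estimated correlation). The number that rose was 2 without WT replicate 1 and 27 without WT replicate 2. Their median log2 fold change stayed at 0.45 to 0.61 with any 1 library left out. Rpl13a averaged 1117 ± 48.6 against 669 ± 65.1 (log2 fold change 0.74 ± 0.10 (SE), adjusted p = 3.1e-04). Many of these genes have near-identical pseudogenes, so their reads are uncertain. Of 106 oxidative phosphorylation genes 56 rose and none fell (70 and 1 adjusted over the list alone). The median was 0.39 (camera, adjusted p = 2.5e-16; adjusted p = 0.24 with an estimated correlation). 29 rose without TCR4 replicate 2, 7 without WT replicate 1 and 21 without WT replicate 2, while the median stayed at 0.31 to 0.45. Ndufs8, a complex I subunit, averaged 977 ± 46.5 against 588 ± 37.4 (log2 fold change 0.73 ± 0.09 (SE), adjusted p = 2.6e-04). Atp5c1 averaged 4098 ± 369 against 2796 ± 159 and Ndufa7 1111 ± 23.9 against 778 ± 34.5. Changes followed a trend with gene length: the median log2 fold change was 0.20 in the fifth of genes with the shortest lengths and -0.12 in the fifth with the longest. Removing this trend took the median of the ribosomal protein genes from 0.52 to 0.38 and that of the oxidative phosphorylation genes from 0.39 to 0.18 (bootstrap interval 0.12 to 0.21). Of 13 mitochondrially encoded genes 4 rose and none fell (8 adjusted over the list alone). The median was 0.39 (camera, adjusted p = 0.0018; adjusted p = 0.46 with an estimated correlation, and 0.057 without TCR4 replicate 1 at the preset one). Without TCR4 replicate 1, 1 rose and 1 fell, without TCR4 replicate 2, WT replicate 1 or WT replicate 2 none rose, and without TCR4 replicate 3 8 rose. With all libraries 8 rose in DESeq2 and in edgeR and 7 in limma-voom. Of 17 glycolysis genes 6 rose and 2 fell, the same adjusted over the list alone (camera, adjusted p = 0.055, and 0.039 without WT replicate 2). Tpi1 averaged 1155 ± 19.1 against 788 ± 72.4. Leaving out WT replicate 1 left 1 glycolysis gene that rose and none that fell, and 1 fell without TCR4 replicate 2, TCR4 replicate 3 or WT replicate 2.

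Further genes changed outside these lists. Gpr15, encoding a homing receptor, averaged 324 ± 59.3 in TCR4 and 26.7 ± 4.82 in WT (log2 fold change 3.55 ± 0.21 (SE), adjusted p = 3.9e-07). Plek, encoding pleckstrin, averaged 3095 ± 228 against 699.7 ± 43.3 (log2 fold change 2.14), Samd3 1739 ± 100.2 against 395 ± 31.2 (2.14) and Ms4a4c 3684 ± 150.04 against 1152 ± 51.8 (1.68). Gprc5b, an orphan receptor gene, averaged 27.5 ± 9.19 in TCR4 and 211 ± 19.1 in WT. The glutamate receptor genes Gria3 and Grm6 averaged 38.7 ± 13.3 against 163 ± 35.4 and 37.1 ± 6.88 against 154 ± 41.8, all lower in TCR4. Zfp990 held 2101 reads over the TCR4 group and 1 over WT, a ratio of 2156 with a 95% counting interval of 387 to 85192. Klk1 held 110 and 3, a ratio of 37.6 (interval 12.5 to 185). These intervals cover counting error only. Zfp990 stood at 965, 1208 and 26.2 normalised reads in TCR4 replicates 1, 2 and 3. limma-voom did not call Zfp990 (adjusted p = 0.37).

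The authors' deposited table gave 3868 genes at an adjusted p under 0.05, 2114 higher and 1754 lower in TCR4. Of these, 3518 were also among the 3784 genes called here, all with the same sign, while 350 were called only in the authors' deposited table and 266 only here. Across the 22633 genes tested here, which are not independent replicates, the log2 fold changes of the authors' deposited table and of limma had a Spearman correlation of 0.973. For Ly6c2 the authors' deposited table gave a log2 fold change of 2.48, and for Ccr9 -1.72.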

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

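edgeR on recovered reads and the fit without X and Y genes were chosen after seeing the data; all other settings had been fixed in advance. Against 3784 genes, the alternatives that kept all libraries gave 3442 to 3953 (2-fold: 723 to 1006 against 971), with edgeR at 3814, DESeq2 at 3906, limma-voom at 3597 and 3669 without X and Y genes. Shared with the 3784 were 3632 genes in edgeR, 3523 in DESeq2 and 3207 with total-count scaling. Leaving out 1 library gave 911 to 3535 genes, and 353 to 1030 with at least 2-fold change; the lowest of each came without WT replicate 1, where 2 WT libraries are left and 906 of the 911 were among the 3784. WT replicate 2 also moved the counts, to 1690 and 577; beyond the smaller number of samples, the cause was not tested. Of 153 named genes 132 passed, 84 of them with each library left out and 123 under every other alternative that gave them an adjusted p. Not every alternative did so for each gene, since some fits leave genes out, such as the TCR and immunoglobulin segments. None of the 132 changed sign where tested.

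Of 33 gene lists 19 passed in camera. With an estimated correlation 0 passed, 8 having an unadjusted p under 0.05; the smallest adjusted p was 0.060. The directional fry test called 21 lists and the mixed one 28. Directional fry called NK receptor (adjusted p = 5.9e-04), cytotoxicity (6.1e-04) and Trbv (3.9e-04) lists. It did not call cell cycle genes (adjusted p = 0.27), B cell markers (0.23), myeloid and dendritic cell markers (0.052) or mitochondrially encoded genes (0.18). Other settings gave 16 to 22 lists, and 19 to 21 with 1 library left out. MHC genes (0.0333) and immunoglobulin segments (0.0172) passed with total-count scaling, regulatory T cell genes (0.0439) and Trav segments (0.0418) with the CPM filter, where apoptosis (0.0609) and cytokine receptor genes (0.0611) did not, glycolysis genes with no low-value filter (0.0462) or a pseudocount of 0.1 (0.0450), and CD4 T cell markers without X and Y genes (0.0289). The difference in Trbv29 share ranged from 23.7 to 25.6 points with 1 library left out, and that of Trav12-2 from 7.34 to 9.61; as CPM the differences were 38.4 and 11.0.

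With a replicate block, 3712 genes (938 with at least 2-fold change) and 20 lists passed. The replicate numbers do not pair the libraries: deviations of libraries with the same number correlated at 0.056, -0.0062 and 0.0076, and only replicate 1 matched best with its own number. Every setting chosen in advance was run. Genes with few reads are limited by depth: Klk1 rests on 3 WT reads and Gapt on 2.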

Other observations

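The gene lists in the next paragraph and the tests of NK cells, the sex of the mice, and the depth, labelling and handling of TCR4 replicate 1 were chosen after the results were seen; the tests of gene length, GC content, scaling and other splits of the libraries were not.

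Some TCR beta joining segments rose while most Trbv segments fell. Of 14 joining segments 6 rose, none fell and 8 did not pass, 4 of these with a negative log2 fold change, with a median log2 fold change of 0.61 (camera, adjusted p = 2.0e-04 over 3 added lists; adjusted p = 0.29 with an estimated correlation), and 4 to 7 rose with 1 library left out; the median was 0.38 without TCR4 replicate 3. Trbj1-2 averaged 386 ± 25.8 normalised reads in TCR4 and 137 ± 15.7 in WT (SD, n = 3). Of 7 genes known to escape X inactivation, Kdm6a and Kdm5c fell (log2 fold changes -0.82 and -0.72) and Utp14a and Pbdc1 rose (0.48 and 0.35); camera gave an adjusted p of 0.43 for the list. The number that fell was 2 with any 1 library left out, and the number that rose was 1 without TCR4 replicate 2 or 3 or WT replicate 2 or 3 and 0 without WT replicate 1. Zfp990 stood at 965, 1208 and 26.2 normalised reads in TCR4 replicates 1, 2 and 3 and at 0.895, 0 and 0 in WT, and Rab6b at 36.9, 40.4 and 316 in TCR4 against 808 to 850 in WT.

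The rise of ribosomal protein genes (median log2 fold change 0.523) was set against technical trends. After a smooth trend on gene length was removed, the median was 0.3811 (bootstrap interval 0.339 to 0.416), so length accounts for part of it but not for most. Removing a trend on GC content left 0.5164, and the lowest median over the scalings was 0.4333, with total-count scaling. A difference between the genotypes remains open and untested beyond this; reads shared with ribosomal pseudogenes were not tested. For oxidative phosphorylation genes the length trend took the median from 0.387 to 0.177 (0.123 to 0.215).

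NK receptor genes rose in every TCR4 library, and NK cells carried through the isolation are a candidate source. In TCR4 replicate 1 the median rise of the 22 called genes was 1.633 and the median of the NK cell markers 0.92 over the WT mean, while Ncr1 stood at 1.00 and Gzma at 202 normalised reads against 9.27 to 12.5 and 155 to 281 in WT. Most NK cell markers stand in the NK receptor list too, so their median is not separate evidence. Ncr1 is near its floor and the level of Gzma in WT would hide a small share, so NK cells and a difference within CD8 T cells cannot be told apart in this library. In TCR4 replicates 2 and 3 the rise averaged 2.079 while Ncr1 (68.7 and 21.5) and Gzma (381 and 286) lay above every WT library, so these 2 sources cannot be told apart there either. Since 0 WT libraries carried Y-linked reads and all TCR4 libraries did, the sex of the mice and the genotype cannot be told apart for any of these genes. A change of CD8 T cell state with genotype remains open.

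TCR4 replicate 1 had low immediate early genes (median -0.51 against 0.55 and 0.48 in TCR4 replicates 2 and 3). Its number of reads was 1.018 times the mean of the other TCR4 libraries, which argues against depth. Its NK receptor rise was 0.7852 times theirs and it carried 6265 Y-linked reads, which argues against a mislabelled WT library. Handling before lysis may differ between libraries, but the labels name 1 batch and no times, so handling and biology cannot be told apart for this library.

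The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Every split but the real one has libraries of both genotypes on both sides. The difference between the genotypes then adds to the spread within each side, so few calls in those splits are favoured in advance. The real split gave 3784 genes and 971 with at least 2-fold change, and the highest other split gave 0 of each in limma, with 423 to 993 genes at an unadjusted p under 0.05 against 6783 in the real one; 1 of the 10 splits, the real one, reached each count. For gene lists the real split gave 19 and the other splits gave 5 to 19, although limma called 0 genes in those. That number was reached by 2 of the 10 splits, the other one setting TCR4 replicate 1 and WT replicates 1 and 3 against the rest. The number of lists that pass in camera at the preset correlation thus does not set the real split apart.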
